A study of Homo sapiens with 6 samples.

How the data were processed

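RNA sequencing was analysed in 6 libraries labelled as MKN45 cells, a line derived from a human gastric adenocarcinoma. Per the labels, 3 samples received an adenovirus carrying a control short hairpin RNA (shRNA) and 3 received an adenovirus carrying an shRNA against GOLPH3. Per the labels' protocols, RNA was isolated on spin columns and made into libraries with a stranded kit that selects messenger RNA. The titles number the samples 1 to 3 in each group and do not say whether the numbers stand for separate cultures, for shared days or, in the GOLPH3 group, for different hairpins. The p-values therefore measure only the spread between these samples, which may be technical.

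The authors deposited 1 table of estimated counts per gene. The values are not all whole: between 64.2% and 65.5% of the values above 0 in a library were whole numbers. Values with a fractional part held 39.8% to 40.9% of the estimated counts in the control libraries. In the GOLPH3 shRNA libraries they held 41% to 43.9%. The submitters' processing notes name the mouse genome build mm10, and each of the 34866 row names begins with ENSMUSG, the prefix of Ensembl mouse gene identifiers, although the labels give the cells as human. The aligner or quantifier, the annotation release, the strand setting and any filter are not given in the sources used here. The counts are taken as human reads assigned to mouse gene models, as the labels and the processing notes read together, but the table alone cannot settle this, and reads from mouse cells under a wrong organism label stay possible. Under the first reading, a gene whose human sequence departs far from the mouse one would collect few reads, so a level is not read here as the abundance of a gene in the cells. Fold changes compare the same identifier (ID) between libraries. Abundance classes, the most abundant IDs and the difference between list means within a library describe assigned counts only.

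The table does not pair its IDs with gene symbols. None of them (0) matched the gene name tables used here, which are for human genes, and no mouse annotation was used here. IDs are therefore printed as the table gives them, without symbol, coordinates or gene structure. GOLPH3 itself, the planned check of the knockdown, and 27 gene lists that had been fixed by symbol before the data were examined (Golgi, glycosylation, mucin, mitogen-activated kinase, stress, cell cycle and other lists) were not analysed here. The fixed rule for naming genes passed over IDs without a symbol; in its place, the 2 largest increases and the 2 largest decreases that met its other criteria are printed. Those criteria were an adjusted p below 0.05, a mean of at least 5 CPM (counts scaled to a common library total) in the higher group, and no overlap between the 3 control and the 3 GOLPH3 shRNA values.

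In place of the lists, 3 lists of cell cycle genes were used that come with mouse Ensembl IDs. The scran package (version 1.30.0) carries gene pairs whose order of expression marks a phase in mouse embryonic stem cells, with 12052 pairs for G1, 6459 for S and 9981 for G2/M. For each of the 667 genes in these pairs, the number of pairs in which it is the lower member was subtracted from the number in which it is the higher one, per phase. A gene was assigned to the phase with the largest net number, if that was at least 10. These lists were chosen after the data were examined. Minimums of 1, 10 and 50 were compared on these libraries before 10 was kept, and the G2/M result of each is given. The members carry no gene names.

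Estimated counts were rounded to whole numbers. IDs were kept by edgeR's filterByExpr (11400 of 34866), which held between 99.7% and 99.8% of each library's counts; 16727 IDs had no reads in any library. Groups were compared with edgeR 4.0.16 in R 4.3.3, using trimmed mean (TMM) factors, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a call at an adjusted p below 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 3 lists, and again with an estimated correlation and with fry. Values per library were compared by exact two-sided permutation, which cannot go below p = 0.1 with 3 against 3. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, a fold minimum, the replicate number as a block, each library left out in turn, only IDs with whole counts in all libraries (with library sizes, factors and dispersions estimated again on them), and libraries thinned to the smallest total; the latter pair was added after the data were examined.

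The edgeR step was tested on simulated data with the 11400 IDs, library sizes and dispersions of this comparison. It recovered 46.3% of 67 IDs changed 1.5-fold, 74.6% of 67 changed 2-fold and 90.9% of 66 changed 4-fold. Of its 153 calls, 12 were IDs that had not been changed. Far fewer IDs were changed in the simulation than were called in the data. The threshold set by the adjustment is stricter in that case, so these shares do not give the recovery in the data. Libraries held 4977645 to 7355140 estimated counts, all GOLPH3 shRNA libraries being smaller than all control libraries. The total number of reads sequenced is not given in the sources used here. In a chi-square comparison, the 6 pairs of libraries within a group differed by 3.29 to 6.52 times the sampling noise, so no pair was treated as 1 library deposited more than once. Counts without molecular identifiers are not independent molecules, and floors cover counting error only.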

Results

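Gene expression was measured by RNA sequencing in samples labelled as MKN45, a human gastric cancer cell line that the study's design describes as lacking the gland mucin MUC6. GOLPH3 is a Golgi protein that binds phosphatidylinositol 4-phosphate and helps to hold glycosyltransferases in the Golgi. The comparison asks how gene expression differs between samples given the GOLPH3 shRNA and samples given the control shRNA. The 3 control libraries held 6694188 ± 577514 estimated counts (mean ± SD) and the 3 GOLPH3 shRNA libraries 5383568 ± 362788, and the most abundant ID took 1.57% to 2.16% of a library. The counts are by mouse gene IDs, although the labels give the cells as human, and the table alone does not settle whether human reads were assigned to mouse gene models or the reads came from mouse cells. The IDs carry no gene symbols, so the level of GOLPH3 in each library, which would check the knockdown, was not analysed here.

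GOLPH3 shRNA was accompanied by changes in 33.9% of the tested gene IDs, in both directions and mostly below 2-fold. Of 11400 IDs tested, 1840 rose, 2030 fell and 7530 did not pass the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The median fold of the IDs that rose was 1.43, and that of the IDs that fell was 1.51. At least 1.5-fold changes were seen in 749 IDs that rose and 1041 that fell, at least 2-fold changes in 265 and 332, and at least 4-fold changes in 32 and 37. The 3 GOLPH3 shRNA values lay wholly above the 3 control values for 96.1% of the IDs that rose, and wholly below them for 97.9% of those that fell. Among all tested IDs, the called ones included, 46.3% had such separate values, where chance gives 10%. The calls were made on the same values, so the high shares among called IDs follow largely from their selection.

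The libraries separated by group. Across the 11400 IDs, Pearson correlations of log2 CPM ran from 0.971 to 0.980 between libraries of 1 group and from 0.948 to 0.959 between libraries of different groups; these are correlations across genes, which are not independent replicates. The first principal component held 48.9% of the variance and the second 15.8%.

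Both directions of change were found at every level of abundance. When the tested IDs were divided into 3 classes of 3800 by mean log2 CPM, the most abundant class (median 112 CPM) had 1024 IDs that rose and 962 that fell, or 52.3% of the class. The middle class (median 24.5 CPM) had 550 that rose and 740 that fell, and the least abundant class (median 5.11 CPM) had 266 and 328, or 15.6%. Fewer small changes can be detected at low counts, so these shares do not show that abundant genes responded more. Of the 20 most abundant IDs, 6 rose, 6 fell and 8 did not pass the test. Together they made up 9.81% ± 0.38 of the control counts and 9.84% ± 0.45 of the GOLPH3 shRNA counts (SD, n = 3, exact permutation p = 0.9).

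**Figure D1:**
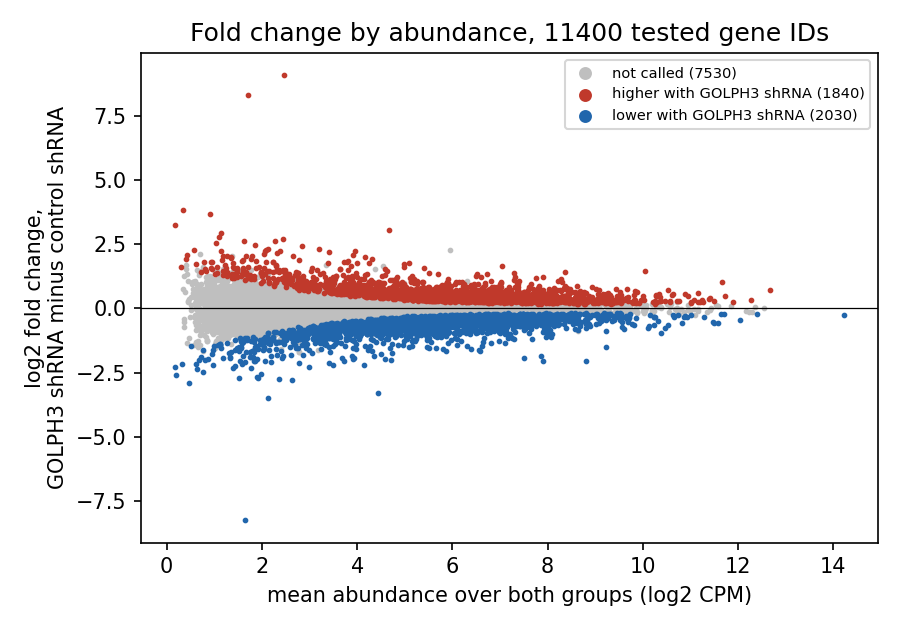
Each point is 1 of the 11400 tested gene IDs, with mean abundance over both groups (log2 CPM) on the x axis and the log2 fold change, GOLPH3 shRNA minus control shRNA, on the y axis. The 1840 IDs that rose and the 2030 that fell lie on both sides of 0 over the whole range of abundance; the 3 points beyond 8 in either direction had no reads in 1 of the groups, and their fitted values depend on the prior count.

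The 2 largest increases were of IDs with no reads in any control library. In all, 5 IDs had no reads in 1 group and at least 5 counts in each library of the other. Another split of the 6 libraries also gave 5 such IDs, so this pattern is not particular to the real grouping. Folds against a group at 0 are given from counts summed over each group, with the group at 0 set to 3 counts. They differ slightly from a ratio of the mean CPM. No reads here means an estimated count that rounds to 0. If reads were divided between gene models, reads that match the ID may still exist, and the folds are then not lower bounds. ENSMUSG00000083027.1 reached 11.1 ± 3.60 CPM with GOLPH3 shRNA (SD, n = 3), from 39 to 83 counts per library. Against the 3 counts it was 75.1-fold higher (edgeR adjusted p = 1.18e-06). ENSMUSG00000101645.1 reached 6.50 ± 3.65 CPM, from 12 to 53 counts, and was 44.7-fold higher in the same way (edgeR adjusted p = 3.00e-05). Among the decreases, ENSMUSG00000075273.4 had 6.24 ± 3.27 CPM in the control libraries and no reads in the GOLPH3 shRNA libraries. With 3 counts set for the latter, it was 34.3-fold lower (edgeR adjusted p = 2.65e-05). ENSMUSG00000078134.1 fell from 39.4 ± 24.3 to 3.88 ± 6.72 CPM, a log2 fold change of -3.30 (SE 0.68, edgeR adjusted p = 0.0014). The last of these rests on scattered values, with 65 counts in GOLPH3 shRNA replicate 2 and 0 in the other GOLPH3 shRNA libraries. Without that library the group was at 0 and the fit gave -10.92, which depends on the prior count. Its log2 fold change was -2.68 without control replicate 2, -2.71 without GOLPH3 shRNA replicate 3, -2.76 without GOLPH3 shRNA replicate 1 and -6.24 with limma-voom, and it was called in each of these. DESeq2 gave -3.34 and did not call this ID (adjusted p = 0.32). All 4 IDs had estimates with a fractional part in each library in which they had reads, as a division of reads between gene models would give. How the estimates were made is not given in the sources used here, and the values of these IDs are uncertain.

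Genes assigned to G2/M by the mouse embryonic stem cell pairs were lower as a list in the GOLPH3 shRNA libraries. The lists for G1 and S were not called by camera, which does not show that their genes were unchanged. Whether the IDs of these lists mark the phases in these samples was not tested. Of 130 tested G2/M marker genes, 49 fell, 19 rose and 62 did not pass the test. Adjusted over the list alone, 50 fell and 21 rose. For comparison, 33.9% of all 11400 tested IDs were called, with 2030 that fell and 1840 that rose. Their median log2 fold change was -0.27, a 1.20-fold lower level, with quartiles at -0.61 and 0.14, and 64.6% of them lay below 0 against 49.9% of all tested IDs. The list stood below the other IDs in the camera test (adjusted p = 0.0023 with the preset correlation, adjusted p = 0.021 with an estimated correlation). With the stricter list of 37 genes that had a net pair number of at least 50, the median was -0.39, and the call was lost with an estimated correlation (adjusted p = 0.15), where it held with the preset one (adjusted p = 0.020). With the wider list of 156 genes at a net pair number of at least 1, the median was -0.17 (camera adjusted p = 0.013, and adjusted p = 0.032 with an estimated correlation).

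The G1 list, with 174 tested genes, had 32 that rose, 45 that fell and 97 that did not pass, and a median log2 fold change of -0.023. Adjusted over the list alone, 33 rose and 46 fell. Its mean was 0.00062, of the opposite sign to the median, and camera gave an adjusted p of 0.57. The fry test, which asks whether the members of a list move on balance in 1 direction and does not set them against other genes, called this list lower (adjusted p = 0.016). The S list, with 111 tested genes, had 16 that rose, 29 that fell and 66 that did not pass (17 and 29 adjusted over the list alone). Its median was -0.070 (camera adjusted p = 0.57, fry adjusted p = 0.060). With an estimated correlation, camera gave an adjusted p of 0.53 for both lists.

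**Figure D2:**
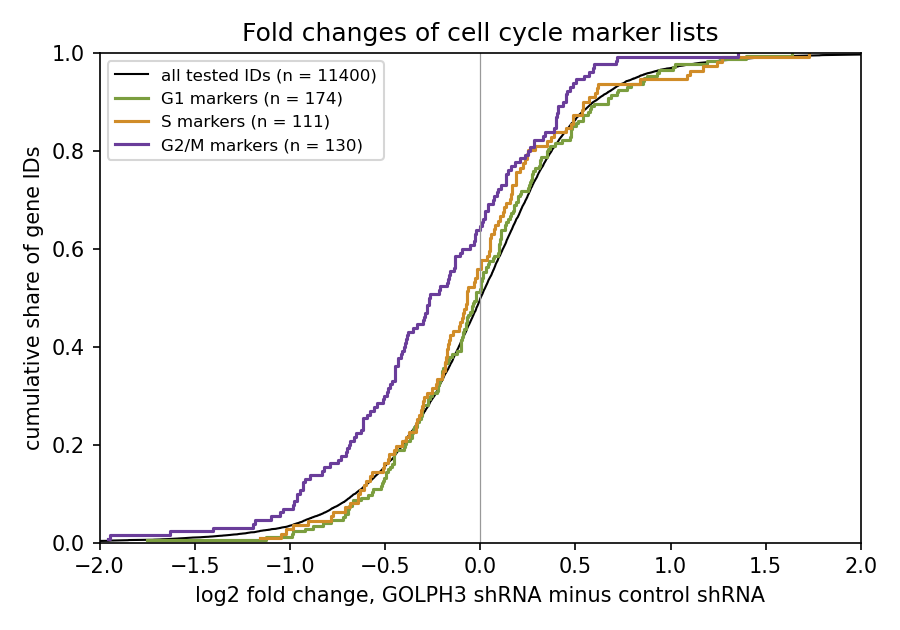
Cumulative share of gene IDs (y axis) by log2 fold change, GOLPH3 shRNA minus control shRNA (x axis, drawn over 2 log2 units to either side of 0), for the G1 (174), S (111) and G2/M (130) marker lists and for all 11400 tested IDs. The G2/M line lies to the left of the others over most of its course, crossing 0 at 64.6%, where the line of all tested IDs crosses at 49.9%.

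The same difference was seen library by library. The mean log2 CPM of the G2/M list in GOLPH3 shRNA replicates 1, 2 and 3 differed by -0.26, -0.22 and -0.26 from the mean of the control libraries, whose SD was 0.016. The mean difference was -0.25 (SD 0.021 over the 3 GOLPH3 shRNA libraries). The exact permutation p was 0.1, the smallest that 3 against 3 allows. For the S list the mean difference was -0.036 (SD 0.017 with GOLPH3 shRNA and 0.024 in the controls, exact permutation p = 0.2). For the G1 list the 3 GOLPH3 shRNA libraries differed from the control mean by between -0.024 and 0.033 (exact permutation p = 1). The G2/M mean less the G1 mean, taken within each library, was -0.34 ± 0.015 in the controls and -0.59 ± 0.046 with GOLPH3 shRNA (SD, n = 3, exact permutation p = 0.1).

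**Figure D3:**
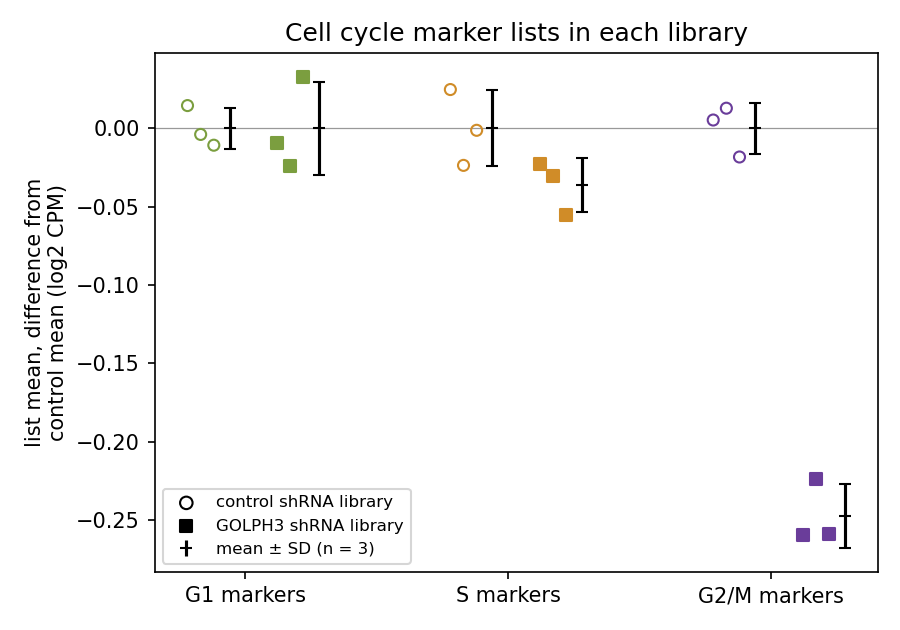
Mean log2 CPM of each cell cycle marker list in each library, as the difference from the mean of the 3 control libraries (y axis, log2 CPM), for the G1, S and G2/M lists (x axis). Open circles are control shRNA libraries, filled squares are GOLPH3 shRNA libraries, and bars give mean ± SD (n = 3); the GOLPH3 shRNA libraries lie at -0.26, -0.22 and -0.26 for G2/M markers and near 0 for the G1 list.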

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

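The tests limited to whole counts or to thinned libraries, and all tests of the marker lists, were chosen after the data were examined. Under the other scalings, filters and tests, 1736 to 1922 IDs were called higher and 1830 to 2222 lower. No call changed direction under these or under the alternatives below, and no scaling moved the median log2 fold change by more than 0.1. With the replicate number as a block 1842 were higher and 2045 lower, and the block changed no call of a list or of a printed ID. Deviations from the group means correlated at 0.032, 0.090 and 0.044 for numbers 1, 2 and 3, and at -0.086 to 0.037 between unlike numbers. Each GOLPH3 shRNA sample correlated best with the control of its own number. Control 1 correlated slightly better with GOLPH3 shRNA replicate 3 (0.037) than with its own number. These small values do not settle whether the numbers stand for pairs, and the main fit took none. Leaving out each library in turn gave 1425 to 1665 higher and 1644 to 1929 lower. A minimum of 1.5-fold left 749 and 1041, by construction. A fit of the 6263 IDs with whole counts alone, with scaling and dispersions estimated again, called 1240 lower and 1245 higher, where the fit of all IDs called 1170 and 1019 of them; the cause of the latter difference was not tested. No list was tested with DESeq2 or limma-voom. The G2/M list was called in all 17 alternatives run for it (medians from -0.39 to -0.17, camera or fry adjusted p from 5.9e-05 to 0.021). It was not called at a net pair number of at least 50 combined with an estimated correlation (camera adjusted p = 0.15). The median of the S list turned to 0.060 at a net pair number of at least 50, where it had 14 genes (adjusted p = 0.99). The G1 list (median -0.023) was called by fry only. Its median was -0.10 at a net pair number of at least 50 (51 genes, camera adjusted p = 0.13). At a net pair number of at least 1 it was -0.0016 (213 genes, camera adjusted p = 0.91). Of the printed IDs, ENSMUSG00000078134.1 was lost with DESeq2 (adjusted p = 0.32), and none could be tested on whole counts, since all 4 have fractional estimates. Planned results for GOLPH3 and for gene lists named by symbol were not run, since the IDs carry no symbols. At the depth, spread and number of these libraries together, simulation recovered 46.3% of changes of 1.5-fold. Far fewer IDs were changed in it than were called in the data, which makes the adjustment stricter. This share therefore does not give the recovery in the data.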

Other observations

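The tests of whole-count IDs against the rest, and of gradation over the marker genes, were chosen after the results they concern had been seen. The test of IDs that changed at least 4-fold was chosen after a test of IDs with no reads in 1 group had proved too small to decide; both are given. Tests of shared reads take fractional estimates as their mark, which the sources used here do not state. Their intervals and Fisher p-values treat IDs as independent, which IDs measured in the same libraries are not.

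The number of IDs that differ between the groups is large for 3 libraries against 3. The real grouping called 3870 IDs, and the highest of the other 9 splits called 0 (1 of 10 splits as large, and 10 splits are too few for a share under 0.05). Each other split mixes both groups, so their difference adds to the spread within it and makes calls unlikely. The splits therefore do not decide whether chance could give as many calls. Thinning every library to the smallest total left 3784 calls, which argues against the difference in counting depth as the main source. Thinning does not undo whatever made the GOLPH3 shRNA libraries smaller, so such a cause was not tested. The share called among IDs with whole counts was 1.07 times that among IDs with fractional estimates (95% interval 1.01 to 1.12). The interval takes IDs as independent, which they are not, so it may be too narrow. The ratio argues against reads shared between gene copies as the main source, if fractional estimates mark them. Fractional values did hold a larger share of the counts in every GOLPH3 shRNA library than in any control library. The median log2 fold change was 0.031 over IDs with fractional estimates and -0.020 over IDs with whole counts. A small contribution of shared reads is therefore not excluded. A response to lower GOLPH3, a response to the hairpin or hairpins that does not pass through GOLPH3 (the labels do not give their number), and a difference in culture or handling between the groups all stay open, since the level of GOLPH3 was not analysed here and the labels give no batch.

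The G2/M markers were still lower when libraries were thinned (median log2 fold change -0.23). Members with whole counts in all libraries had a median of -0.31. None of 10000 random lists matched on mean expression reached the observed -0.27, the lowest being -0.20. These values argue against counting depth, a trend with expression level and, if fractional estimates mark them, shared reads as the whole source. Across the 558 tested genes of the marker pairs, a higher net G2/M pair number went with a lower fold change, weakly (Spearman rho -0.12, Pearson r -0.11, permutation p = 0.004; genes are not independent replicates). The same pair number defined the list, so this correlation largely restates its lower level. A smaller share of cells in G2 and M and a lower expression of these genes within each cell were not tested against each other, and both stay open. Whether these IDs mark G2 and M in these samples was not tested either. The hairpin, culture and handling explanations given above for the calls stay open for this list too.

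The test did not find IDs with fractional estimates to be more frequent among the largest changes. Of the 69 IDs that changed at least 4-fold, 43.5% had a fractional estimate, against 49.2% of 1380 IDs matched on total count (odds ratio 0.79, 95% interval 0.47 to 1.33, Fisher's exact test p = 0.39). Of the 5 IDs with no reads in 1 group and at least 5 in each library of the other, 4 had one, against 48 of 100 matched IDs (odds ratio 4.28, 95% interval 0.41 to 217, Fisher's exact test p = 0.21), an interval too wide to decide. The highest number of such IDs in the other splits of the 6 libraries was also 5. The printed IDs with no reads in 1 group are among the 5 of the real grouping. No biological explanation was tested for these IDs.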
